A study of Nannochloropsis oceanica with 12 samples.

How the data were processed

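The series compares chromatin of Nannochloropsis oceanica IMET1 from nitrogen-replete and nitrogen-deprived cultures. Per the labels' protocols, cells were grown at 25 °C under continuous light of 50 µmol photons per square metre per second with 1.5% CO2. They were washed, resuspended at an OD750 of 2.5 in 800 mL of medium with or without nitrogen, in 3 cultures per condition, and collected after 72 hours. Cells were fixed with 1% formaldehyde, nuclei were isolated, and single-end reads of 150 bp were sequenced. Groups follow the labels' treatment and antibody fields, which give 3 lactyllysine ChIP libraries and 3 libraries without antibody per condition. The submitters' processing notes name Trim Galore, BWA, Picard, deepTools and MACS2, with no versions. The genome build, the tool that made the differential table, and whether a control was subtracted are not given in the sources used here.

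The single file is a table of differential peaks. It holds log2 mean levels per peak over both groups, over deprived and over replete libraries, as the authors deposited them. It also holds the authors' deposited log2 fold change, p-value and FDR per peak. The fold change has the sign of deprived minus replete in all 5375 peaks, which was checked against the group means. A group mean under 1 is listed as 0 on the log2 scale. Dividing FDR times rank by p gave 5389 within 0.5 in 4992 peaks, taken as the number tested. The highest listed FDR is 0.0499, so a looser threshold of 0.1 could not be tried. Coordinates are as the authors' table gives them.

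The group means proved to be sums of whole reads. Each of the 3 libraries adds its reads times what 1 of its reads is worth, and the sum is divided by 3. The 3 worths of a group were found as the steps that explain the 40 lowest distinct values, searching steps from 0.2 to 0.6. Means listed at 0 (1428 replete and 5 deprived) were first rebuilt from the mean over both groups and the other group's mean. Where the rebuilt mean was about 0, in 1179 replete and 5 deprived peaks, all 3 libraries were set to 0 reads without solving. Every other mean of the 5375 peaks had exactly 1 set of 3 whole numbers that gave it. The relative tolerance was 4e-13 plus 1e-12, and for rebuilt means it was scaled to the other group's level. Of 500 decoy values per group with the decimals altered, 0 could be solved. On simulated data of 600 peaks per group the reads came back exactly in 100% of peaks. The worths were 0.969, 1.05 and 1.13 normalised reads in the deprived and 0.888, 0.902 and 1.12 in the replete libraries. The inverse worths, the factors by which reads were divided, average 1 over the 6 libraries, and the highest is 1.27 times the lowest. Whether they follow total library depth could not be checked. The libraries are named A, B and C by ascending worth, since the table does not tie them to replicate numbers. The recovered reads may be what was left after steps that the sources used here do not describe, so a recovered 0 is the value that entered the authors' mean and need not mean that no read was sequenced there. Folds against a group with 0 in all 3 libraries are given as bounds against a floor of 3 reads over the group, a mean of 0.969 normalised reads for replete and 1.05 for deprived cells. Such floors cover counting error only, they rest on the authors' scaling unless another is named, and they give no bound for unsubtracted reads if a background was subtracted.

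Calls are the authors' own, at an FDR under 0.05. The tests chosen before the data were examined were an exact binomial test of the directions, a permutation test of the difference of median levels with 100000 permutations, and 2 permutation tests along chromosomes. These were a chi-square over chromosomes with at least 10 listed peaks, with 100000 permutations, and the share of neighbours with the same direction, with 10000 permutations within chromosomes. limma 3.58.1 (R 4.3.3) on log2 of normalised recovered reads plus a pseudocount of 1, with 1 prior variance for all peaks and Benjamini-Hochberg adjustment, was added after seeing the data as a test with values per library. Pseudocounts of 0.1 and 20, 2 other scalings, a variance trend and each library left out were tried with it. On simulated libraries of 5375 peaks, 3 against 3, limma recovered 97 of 100 peaks changed 2-fold and 100 of 100 changed 4-fold. There were 13 false calls. Most simulated peaks were left unchanged, whereas nearly all listed peaks differ and many replete values stand at 0. The simulated rates therefore describe the simulation and may not hold for these data. The folds of limma are differences of mean log2(value + pseudocount). The pseudocount makes them smaller where a whole group is near 0, and a single library at 0 can make them larger than the ratio of group means. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

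Named peaks were to be chosen by assigned gene, and failing that as the 2 peaks with the largest fold change per direction. The gene table used here (assembly ASM5162214v2) holds 160 genes, 35 mitochondrial and 125 plastid, and 0 on nuclear chromosomes. Peaks were therefore assigned to no gene. The 16 gene lists fixed beforehand, the classes of gene location and the counts per gene were not run, and the fallback rule was used.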

Results

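Lysine lactylation is a modification in which a lactyl group is attached to the side chain of lysine, on histones among other proteins. It was profiled on chromatin of Nannochloropsis oceanica strain IMET1, a unicellular marine alga known for storing oil as triacylglycerol when nitrogen runs out. Cells grown to an OD750 of 2.5 were moved for 72 hours into medium with nitrogen (replete) or without it (deprived). Chromatin was then precipitated with an antibody against L-lactyllysine and sequenced. The series holds 12 libraries in 4 groups of 3, namely lactyllysine ChIP from replete cells, lactyllysine ChIP from deprived cells, and libraries made without antibody from each condition. The labels describe 3 cultures per condition. Values of the 6 libraries without antibody were not analysed here. The data are the authors' deposited table of 5375 peaks that passed an FDR of 0.05 between deprived and replete ChIP libraries, each 401 bp wide, on 30 chromosomes. The FDR values fit a test over 5389 peaks, so 99.7% of the tested peaks are listed and 14 are not.

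The levels in that table are group means per peak, in reads scaled between libraries by the authors. Whole reads per library were recovered from them, as described with the processing, and the libraries are called A, B and C within a group because the table does not say which replicate is which. The deprived libraries held 1620064, 1371356 and 1351261 reads in the listed peaks. The replete libraries held 89564, 30954 and 19082. The authors' scaling divided reads by factors of 1.03, 0.955 and 0.884 in the deprived libraries and of 1.13, 1.11 and 0.895 in the replete ones. Total library depth was not analysed here, so whether these factors follow it is not known. Reads in the listed peaks were 31.1-fold more in the deprived group, and they ranged 1.20-fold between the deprived and 4.69-fold between the replete libraries.

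The first question was how the lactyllysine mark differed between nitrogen deprivation and repletion. A total of 5331 peaks were higher in deprived cells and 44 were lower in the authors' deposited table. The higher peaks had a median level of 265.7 normalised reads in deprived cells (quartiles 195.4 and 357.0, range 78.1 to 1049) in the authors' deposited table. Their median in replete cells was 5.33 there (upper quartile 10.99, highest 72.2), and 1428 of them had a replete mean listed at 0 on the log2 scale, which stands for means under 1. The lower peaks had the opposite profile, with a median of 105.0 normalised reads in replete cells (range 69.3 to 149) and 9.997 in deprived cells (highest 31.5) in the authors' deposited table.

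**Figure D1:**
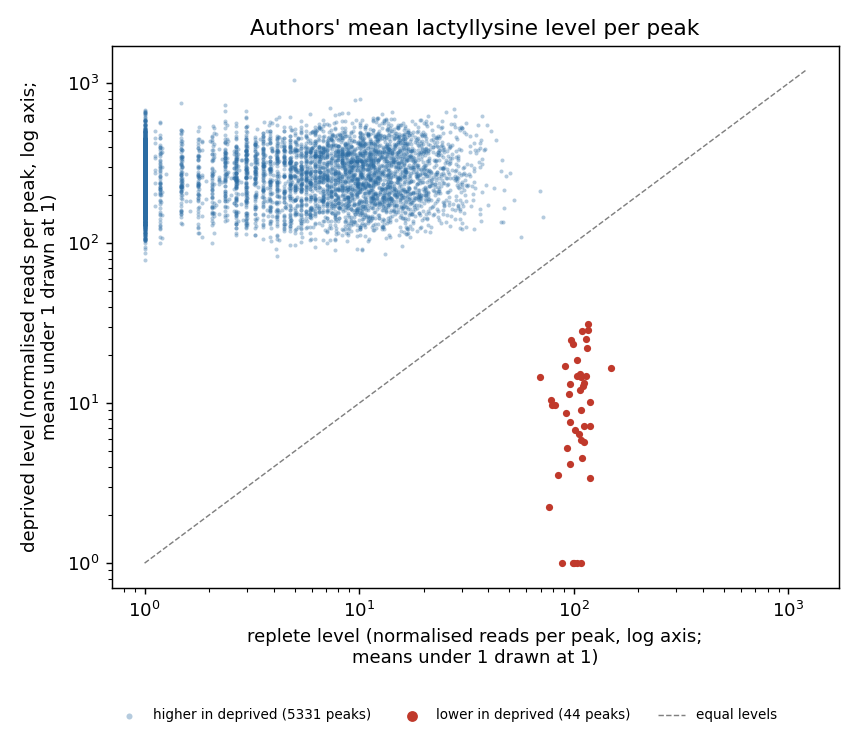
Mean lactyllysine level of each of the 5375 listed peaks in replete cells (horizontal axis) and deprived cells (vertical axis), in normalised reads on log axes, as the authors' deposited table gives the group means; means under 1 are drawn at 1. The 5331 higher peaks (blue) lie above the line of equal levels, between 78.1 and 1049 in deprived cells, and the 44 lower peaks (red) lie below it, between 69.3 and 149 in replete cells.

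Most changes were large under the authors' scaling. The authors' deposited table gave a median log2 fold change of 5.50 for the higher peaks (quartiles 4.42 and 8.46) and of -3.07 for the lower peaks (quartiles -4.11 and -2.74). Of the higher peaks, 5321 had a log2 fold change of at least 2 and 4486 of at least 4 in the authors' deposited table. Among lower peaks 41 and 12 reached those sizes downward. The fitted folds depend on how values of 0 are treated, since all 3 replete libraries stood at 0 in 1179 of the higher peaks. Against a floor of 3 reads over the replete group, those 1179 peaks were at least 80.6-fold to at least 698-fold higher in deprived cells, with a median bound of 267-fold under the authors' scaling. With libraries scaled to equal reads in the listed peaks the same bounds ran from 1.61-fold to 14.0-fold, with a median of 5.36-fold. Bounds of this kind refer to the values that entered the authors' means. Whether a background was subtracted from those is not given in the sources used here, and if it was, the bounds do not hold for the unsubtracted reads. Under the authors' scaling, the other 4152 higher peaks had a median ratio of group means of 36.3 (quartiles 20.2 and 76.5). That ratio was not computed with equal reads in the listed peaks, the scaling that lowered the median bound from 267-fold to 5.36-fold.

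All 3 deprived libraries lay above all 3 replete libraries in 5331 of 5331 higher peaks, and all 3 replete libraries above all 3 deprived ones in 44 of 44 lower peaks. Chance gives such a separation in 5% of unselected peaks for a given direction with 3 against 3. The listed peaks were selected by a test of the same libraries, so these counts only describe the list. The deprived libraries varied little among themselves, with a median coefficient of variation of 9.01% per higher peak. Median reads per higher peak were 285, 241 and 238 in deprived libraries A, B and C and 11, 0 and 0 in replete libraries A, B and C. Replete library A stood at 0 in 30.4% of the higher peaks, library B in 66.7% and library C in 75.7%. Lower peaks were seen in every replete library, with 94 to 198 reads in A, 62 to 140 in B and 20 to 130 in C, against at most 53, 41 and 43 in the deprived libraries.

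**Figure D2:**
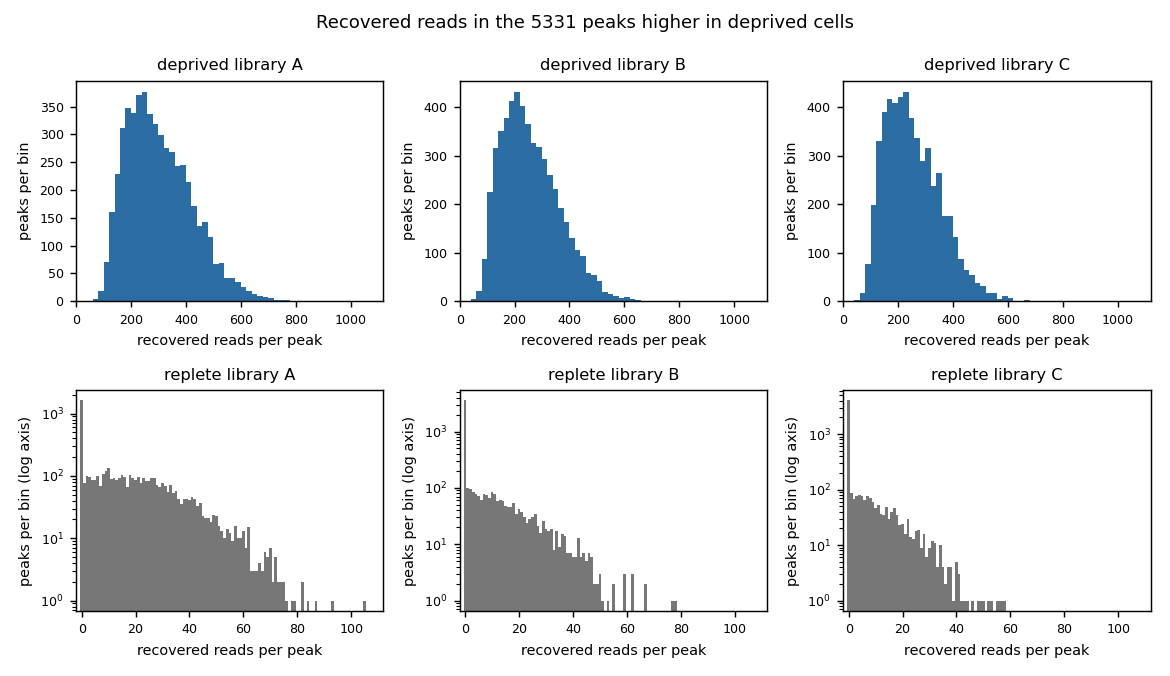
Number of peaks (vertical axis) by recovered reads per peak (horizontal axis) in each library, for the 5331 higher peaks, in bins of 20 reads for the deprived libraries (top, linear vertical axis) and of 1 read for the replete libraries (bottom, log vertical axis). Medians were 285, 241 and 238 reads in the deprived libraries, while 30.4%, 66.7% and 75.7% of the peaks stood at 0 in the replete libraries.

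The scaling between libraries bears on this balance, because the authors' scaling does not equalise the reads in peaks. limma on the recovered reads with the authors' scaling and a pseudocount of 1 called 5359 peaks at an adjusted p under 0.05, with 5318 higher and 41 lower. After the libraries were scaled to equal reads in the listed peaks, limma called 1334 peaks higher and 211 lower, and 167 of these 211 are listed as higher in the authors' deposited table. That scaling moved the median log2 fold change over all peaks from 6.57 to 4.28. The pseudocount stayed at 1 there, although 1 replete read then counted for far more than 1 normalised read. Zeros in replete libraries therefore weigh heavily in these folds and in the higher calls. Equal totals also remove any difference in total reads between the groups, so the 4.28 does not measure a remaining rise. With every library's median set equal (median log2 fold change -0.34), limma called 0 peaks higher and 43 lower, and 818 peaks had an unadjusted p under 0.05. The centring largely fixes that outcome, since replete libraries B and C have a median of 0 reads and cannot fall below it.

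The second question was whether the mark moved mostly one way. Higher peaks made up 99.2% of the list (exact Clopper-Pearson 95% interval 98.9% to 99.4%), and the log10 of the 2-sided exact binomial p against an even split was -1508. Peaks are not independent replicates, so interval and p describe this list and cover counting error only. How sites came to be tested as peaks was not examined here. Every higher peak had a deprived level of at least 78.1 normalised reads, and every lower peak a replete level of at least 69.3. Sites low in both groups are therefore absent. If peaks were called in these same libraries, the share partly reflects which group supplied them, and it does not describe the genome. In limma, the share among called peaks was 86.3% with libraries scaled to equal reads in the listed peaks. Replete zeros against a small pseudocount weigh heavily in the higher calls there. That share therefore does not show how far the direction holds under equal reads. The share of higher peaks was 0% of 43 called peaks with library medians set equal, where the centring largely fixes the split.

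The extremes are given by the 2 peaks with the largest fold change per direction, named by position because no peak was assigned to a gene here. The genome build is not given in the sources used here. The largest rise was peak_5382 on chromosome 9 from 1144778 to 1145178, with a log2 fold change of 11.49 and an FDR of 1.06e-19 in the authors' deposited table. It had 737, 594 and 614 reads in the deprived libraries and 0 in each replete library, at least 698-fold higher. Next was peak_4911 on chromosome 7 from 1188651 to 1189051, with a log2 fold change of 11.48 and an FDR of 1.17e-19 in the authors' deposited table. It had 740, 594 and 594 reads in the deprived libraries and 0 in each replete one, at least 692-fold higher. The largest fall was peak_2230 on chromosome 2 from 818217 to 818617, with a log2 fold change of -8.78 and an FDR of 2.71e-12 in the authors' deposited table. It had 153, 117 and 73 reads in the replete libraries and 0 in each deprived library, at least 103-fold lower in deprived cells. In peak_4968 on chromosome 8 from 272034 to 272434 the log2 fold change was -8.73 and the FDR 3.35e-12 in the authors' deposited table. It had 148, 88 and 90 reads in the replete libraries and 0 in each deprived one, at least 98.9-fold lower. These bounds hold for the authors' scaling. With equal reads in the listed peaks they were 14.0-fold for peak_5382 and 13.9-fold for peak_4911, and 4464-fold for peak_2230 and 4415-fold for peak_4968.

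Both of those lower peaks belong to a set of 5 that stood at 0 in every deprived library. The other 3, chosen after their values were seen, lay on chromosome 1 from 1045309 to 1045709, on chromosome 1 from 1328384 to 1328784 and on chromosome 3 from 110461 to 110861. They were at least 84.3-fold, 94.1-fold and 95.2-fold lower in deprived cells against a floor of 3 reads over the deprived group, under the authors' scaling. With equal reads in the listed peaks these bounds were 3602-fold, 4716-fold and 4282-fold. The largest of them then passed the 4464-fold of peak_2230, so the order of the falls depends on the scaling. The strongest mark in deprived cells, also picked by its value, was on chromosome 6 from 1282626 to 1283026. It reached 1049 normalised reads against 4.98 in replete cells in the authors' deposited table, with 1097, 1020 and 897 reads against 8, 0 and 7.

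Whether lower or higher peaks had more signal depended on the scaling. Under the authors' scaling the median mean level over both groups was 5.85 on the log2 scale for lower and 7.09 for higher peaks in the authors' deposited table. The difference of -1.24 had a 2-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Compared by the level of the group in which each was higher, the difference was -1.34, with a permutation p of 1e-05, again the smallest possible. With libraries scaled to equal reads in the listed peaks both differences turned, to 3.44 and 4.15, each with a permutation p of 1e-05. Peaks are not independent replicates, so these p-values describe this list only and do not measure the spread between cultures. All 5375 peaks have the same width of 401 bp, so widths could not be compared.

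The third question was whether the changes ran in blocks along the genome. Higher peaks covered all 30 chromosomes, at 178 listed peaks per Mb between the outermost peaks, from 146 per Mb on chromosome 23 to 205 per Mb on chromosome 2. Median deprived levels per chromosome ranged from 241 normalised reads on chromosome 16 to 293 on chromosome 24. The 44 lower peaks were spread over 23 chromosomes, with 4 each on chromosomes 1, 2, 6 and 7, and none on chromosomes 12, 13, 16, 24, 26, 29 and 30. The split of higher and lower peaks did not differ detectably between chromosomes (chi-square 19.3, permutation p 0.919). Neighbouring listed peaks had the same direction in 98.4% of 5345 pairs, where permutation within chromosomes gave a mean of 98.4% (2-sided permutation p 0.9303). No pair of neighbouring listed peaks was lower on both sides. With 44 lower peaks, these tests had few events to work with.

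**Figure D3:**
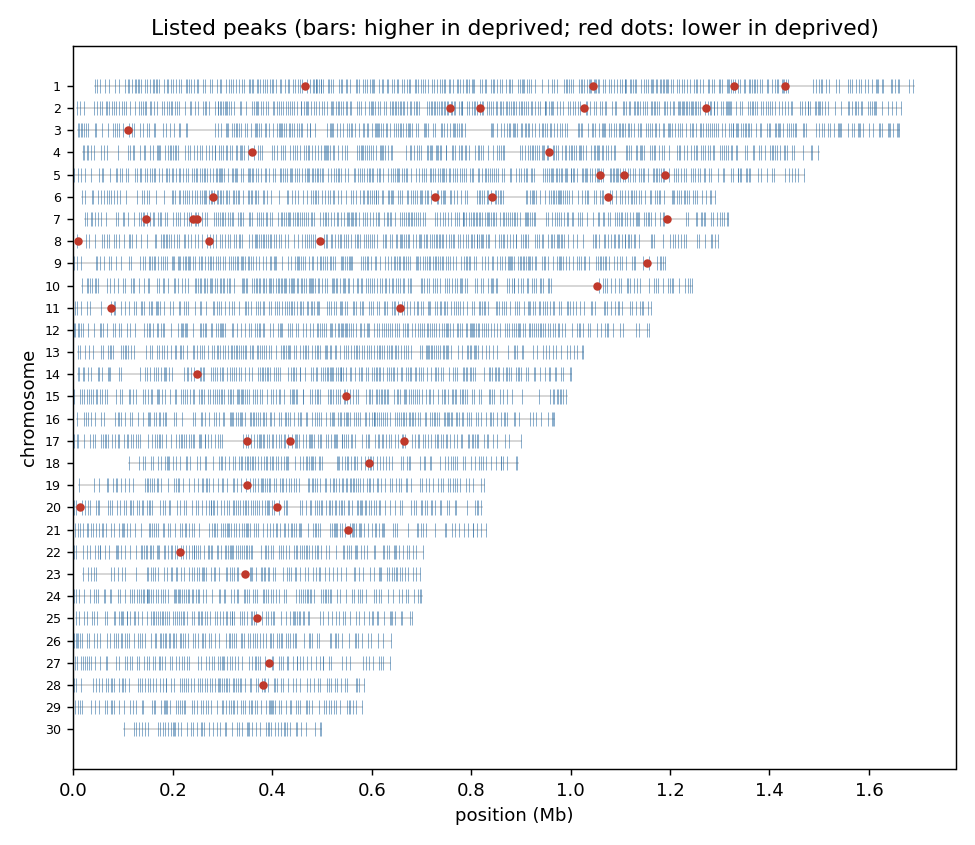
Position in Mb (horizontal axis) of the 5375 listed peaks on the 30 chromosomes (vertical axis). Each blue bar is a peak higher in deprived cells and each red dot one of the 44 lower peaks, which occur on 23 chromosomes, with at most 4 on any chromosome.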

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

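The limma fits with pseudocounts 1 and 20, the 2 other scalings and the variance trend were chosen after seeing the data. There were 65 alternative values for the counts, the share of higher peaks and the tests of level and position. Of these, 55 kept their direction and their side of the threshold (for counts, stayed within 1.5 times the reported one). All 40 for the 4 named peaks did so too. Their choice nearly fixed this, since they have the largest folds and stand at 0 in all libraries of 1 group. Those 40 leave out the variance trend and equal library medians. With equal medians limma called 0 peaks higher, so the named higher peaks lost their call there. Another 7 could not change, since adjusting over the listed peaks, a 1.5-fold minimum and a minimum of 20 peaks per chromosome remove nothing from this list. With libraries scaled to equal reads in the listed peaks, limma called 1545 peaks, 1334 higher and 211 lower. Replete zeros against a pseudocount of 1 weigh heavily in those calls. The level differences between lower and higher peaks turned under that scaling from -1.24 to 3.44 (mean level) and from -1.34 to 4.15 (level in the group where a peak is higher). With library medians set equal limma called 43, of which 0% were higher (0 peaks, 818 at an unadjusted p under 0.05), an outcome the centring largely fixes, with replete medians at 0 reads in B and C. At or above the lower quartile of mean level 0 lower peaks are listed, because all 44 have low mean levels under the authors' scaling. Leaving out each library in turn gave 4858 to 5347 called peaks, 4820 to 5318 higher and 29 to 38 lower, with 99.2% to 99.5% higher; the 29 came without replete library A. With a variance trend that count was 24, where the prior variance of lower peaks reached 1148. Pseudocounts of 0.1 and 20 gave 4989 and 5375 called peaks. An FDR under 0.01 left 5183 higher and 36 lower peaks. No paired analysis was possible because the deposited columns carry no replicate numbers. A looser FDR and the width filter gave no value of their own; alternatives by gene, gene location or count model were not run. The replete libraries, at 19082 to 89564 reads in the peaks, limit the folds to bounds where they stand at 0.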

Other observations

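All explanations weighed here, and the tests of distance between peaks, were chosen after the result was seen. The listed peaks were spaced along the chromosomes at a median of 4684 bp between neighbouring starts, with 5% closer than 1949 bp and 5% farther than 12420 bp. The longest stretch without a listed peak ran on chromosome 10 from 961471 to 1053438, a length of 91968 bp, and was followed by a peak that was lower in deprived cells (log2 fold change -1.94 in the authors' deposited table). Next came chromosome 3 from 228435 to 284622 and from 787507 to 840015, 56188 and 52509 bp long. Across the higher peaks, the deprived level rose with the distance to the nearest listed peak (Spearman's rho 0.139 across peaks, permutation p 0.0001, the smallest that 10000 permutations can give; peaks are not independent replicates). Median deprived levels were 241, 267, 273 and 287 normalised reads in 4 equal parts of the peaks from nearest to farthest, whose median distances were 2041, 2868, 3941 and 5919 bp. Levels of neighbouring peaks were not related (rho -0.00579).

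Lower peaks lay closer to another listed peak than higher peaks did, at a median of 2188.5 against 3381 bp. The 2-sided permutation p was 0.00065 across peaks, which are not independent replicates. The low mean level of lower peaks under the authors' scaling was tested as an explanation, since weaker peaks were also closer together. Draws of higher peaks matched on mean level, from the 50 nearest in level per lower peak, had a median distance of 2908 bp (95% of draws from 2467 to 3448 bp), which argues against level as the whole explanation. These comparisons set lower peaks against higher peaks, not against sites placed at random among them. They cannot show whether lower peaks lie closer than such sites would, so they do not point to a link with regions that gain the mark. Whether lower peaks mark sites beside such regions was not tested. Distances from sites placed at random, peak positions relative to genes and values of the libraries without antibody were not analysed here.

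Replete libraries stood at exactly 0 in many higher peaks, with a shape unlike that of low read counts from 1 negative binomial distribution. A negative binomial fitted to each replete library gave too many peaks with 1 to 5 reads. The observed numbers were 447, 428 and 387 against 1448, 944 and 737, a ratio of at most 0.525. This argues against chance zeros of low counts that follow 1 such distribution for all higher peaks of a library. Mixtures of distributions were not tested. A normal curve fitted only to the values above 0 put 32.8%, 74.3% and 79.0% of peaks below 0, where 30.4%, 66.7% and 75.7% were observed. The curve was too high in all 3 libraries, by at most 7.59 percentage points. This is consistent with values from which a background was subtracted and negative results set to 0. Whether such a step was taken is not given in the sources used here, and if it was, folds against replete cells may be larger than those of the unsubtracted signal.

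Nearly every listed peak was higher in deprived cells, and deeper deprived libraries stay open: the authors' scaling factors had a deprived to replete ratio of 0.917, but whether they follow total depth could not be checked. A replete profile equal to the deprived one at a single lower strength would give a slope of about 0.0108 of replete on deprived level, after allowing for zeros, and the slope was 0.00378 (95% bootstrap interval 0.00176 to 0.00563). Across higher peaks, replete libraries were related to each other (Spearman's rho 0.243 to 0.283) and hardly to the deprived ones (0.0325 to 0.045), so most of what they share is not a copy of the deprived profile. A much weaker copy beneath a remaining background stays open, because background left in the mean replete level could raise the expected slope, and so a weaker replete precipitation and a weaker mark in replete cells, the biological explanation, cannot be told apart here. Of the 10 splits of the 6 libraries, 1, the real one, gave as many called peaks in limma (5359, highest other 0), but 10 splits are too few for a share under 0.05.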
